A study of Chlamydomonas reinhardtii with 9 samples.

How the data were processed

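The series measured messenger RNA by sequencing in 9 libraries of the single-celled green alga Chlamydomonas reinhardtii: 3 of wild type, 3 of the mutant crpaf1-1 and 3 of the mutant crskip-1. Per the labels, all cultures were of strain CC5325, grew in liquid TAP, an acetate-containing medium, at 22 °C under 14 h of light and 10 h of darkness, and were taken late in G1. The labels' protocols describe oligo(dT) selection of RNA with polyadenylated tails and paired-end sequencing on a NovaSeq instrument, while the labels' molecule field reads genomic DNA. The protocol was followed here, and the values are treated as expression. Nothing in the labels says whether the replicates were separate cultures, so p-values measure the spread between these libraries, which may be technical.

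The authors deposited 1 table of raw counts per library, not normalized, with whole numbers for 14621 genes. Per the submitters' processing notes, Bowtie2 and featureCounts were used; their versions are not given in the sources used here. Per the file headers, the counted alignments were uniquely mapped and had duplicates removed. Removal of duplicates lowers the counts of highly expressed genes more than those of others, and unique mapping leaves out reads shared by near-identical genes. Bowtie2 does not split a read across an intron, so reads over exon junctions may have been lost, which affects genes with short exons most. Whether strand was used, and whether reads or fragments were counted, is not given in the sources used here. A printed gene that overlaps one on the opposite strand is therefore reported as uncertain.

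Gene IDs (as in Cre12.g537250_4532.v6.1) end in a suffix that names a gene set, and the tables list each gene's exons with chromosome, start, end and strand. Coordinates are printed as the deposited files give them, and the assembly is named in the sources used here only by that suffix. Exons that overlapped within a gene were merged, and the merged pieces are called exon blocks. Their summed length equalled the deposited gene length for all 14621 genes. The reference table used for gene names, of assembly Chlamydomonas_reinhardtii_v5.5, listed 17742 genes. Of the deposited IDs, 13245 matched a locus tag in it, and 0 of its genes carried a symbol other than the locus tag. Genes could therefore not be given names, and the deposited files do not pair IDs with names. The mutated genes, the kinase CDKB and the gene lists fixed beforehand (cell cycle, histones, cilia, photosynthesis, stress, mating) were not analysed here, so no library label was checked by the level of its mutated gene.

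Replicate 1 of each group was sequenced in lane 3 and replicates 2 and 3 in lane 2, per the file headers. The lanes are thus balanced over the groups. Total counts ranged from 13907142 to 19725439 per library. Of the listed genes, 112 had no count in any library, and 1245, including those, fell below the filter on low counts. The genes below the filter held 0.019% of all counts. Deposited columns of other samples numbered 0.

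Groups were compared with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, on the counts as deposited, with TMM scaling, the default filterByExpr filter and all 9 libraries in 1 fit without covariates. A gene is said to be called, higher or lower when its Benjamini-Hochberg adjusted p was under 0.05. Standard errors (SE) are the log2 fold change divided by the square root of F. CPM values of single genes use the TMM-scaled library sizes, and CPM values of the plastome and mitogenome as a whole use each library's total over all listed genes, without TMM. Sets of genes (the plastome, which is the chloroplast genome, the mitogenome, each of the 17 chromosomes, genes with a single exon block and genes without a v5.5 locus tag; 21 sets per comparison) were tested with camera and fry of limma 3.58.1, with the adjustment made over the 21 sets. Camera compares a set with all other genes and used a preset correlation of 0.01, then an estimated one. Fry tests whether a set's genes move, on balance, one way, without comparing the set with other genes. In crpaf1-1 against wild type fry passed for all 17 chromosomes (adjusted p 5.44e-05 to 0.0391) and the mitogenome (adjusted p = 0.00665). It did not pass there for the plastome (adjusted p = 0.817). In crskip-1 against wild type fry passed for the plastome (adjusted p = 0.0235). There it passed for some chromosomes (such as 6, adjusted p = 0.000735) and not for others (such as 8, adjusted p = 0.898). Since whole chromosomes passed, fry is not used further. The organelle share of counts was planned as a sign of RNA selection; the tests on sets were chosen after the data were examined, in place of the gene lists.

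Correlations of log2 fold change with exon blocks, exonic length and span are Spearman's, over 13376 genes, with two-sided permutation tests of 100000 resamples and adjustment over the 9 correlations. Genes are not independent replicates, so these p-values describe the set of genes and not new cultures. Values per library were compared with two-sided exact permutation tests. With 3 libraries against 3, the smallest p such a test can give is 0.1. The overlap of the mutants' changes, which rests on the same wild-type libraries, was set beside 20 simulations of unchanged groups sharing those controls. Other results found in both mutants (gene structure, organelle counts, neighbouring genes, genes near 0 counts) were not.

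The rule for printed genes was fixed before the data were examined. For each comparison with wild type it took the 2 highest and 2 lowest log2 fold changes among called genes with a mean of at least 5 CPM and no overlap between the groups' CPM values. For crpaf1-1 against crskip-1 the rule set the 5 highest and 5 lowest. There the 2 highest and 2 lowest were printed by the same criteria, so that part of the rule was changed. The further genes the rule would have named in the comparisons with wild type all needed a gene name. The steps were tested on simulated data for crpaf1-1 against wild type, with 200 of 13218 genes changed, 50 at each fold. The test recovered 48% of the genes changed by log2 0.32, 76% of the genes changed 1.5-fold, 98% of those changed 2-fold and 98% of those changed 4-fold, with 11 false calls.

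Alternatives were DESeq2 1.42.0, upper-quartile scaling, library size alone, no filter, a filter of 5 CPM in at least 3 libraries, only the 6 libraries compared, the replicate number as a block, a 2-fold threshold, each library left out in turn, and correlations with length and mean expression held fixed. Lane as a term, lane 2 alone, the correlation with exonic length at fixed exon number and mean expression, the organelle counts under every alternative, adjacent pairs without overlap, and the values of printed genes outside the comparison that named them were added after the data were examined.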

Results

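Polyadenylated RNA was sequenced from wild-type Chlamydomonas reinhardtii and from the mutants crpaf1-1 and crskip-1, with 3 libraries per group, all harvested late in G1, before the cells divide. PAF1 is a subunit of a complex that travels with RNA polymerase II during transcription elongation, and SKIP is a conserved protein of the spliceosome that also acts in transcription. The title of the series places both in 1 module with the cell cycle kinase CDKB. Wild-type libraries held 14006299 to 16812251 counts, crpaf1-1 libraries 16876166 to 19725439 and crskip-1 libraries 13907142 to 16122105. The 20 most abundant genes took 6.74 to 8.93% of each library. Log CPM values correlated at 0.993 to 0.995 between replicates (Pearson's r across genes) and at 0.958 to 0.971 between libraries of different groups. Replicates differed by more than counting noise, with a chi-square per degree of freedom of 2.45 to 4.25, so none was treated as a library deposited more than once. The first 2 principal components held 47.3% and 35.8% of the variance and the third 4.0%.

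The comparison of crpaf1-1 with wild type asks which transcripts depend on PAF1. Of 13376 genes tested, 7806 (58.4%) changed: 3819 were higher and 3987 lower in the mutant. Most changes were small, with a median absolute log2 fold change of 0.45 among called genes. Among the 1178 genes that changed at least 2-fold, 843 (71.6%) were lower and 335 higher. Of the mitogenome's genes, all 8 tested were higher in crpaf1-1, with a median log2 fold change of 0.73 (SD over genes 0.32).

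The highest fold change under the naming rule in crpaf1-1 was that of Cre12.g537250_4532.v6.1, on the minus strand of chromosome 12 at 6393551 to 6404504, with 19 exon blocks. It measured 1.46 ± 0.456 CPM in wild type and 41.2 ± 10.5 CPM in crpaf1-1 (SD, n = 3 each), a 28.3-fold rise (log2 4.82, SE 0.24). Cre02.g145750_4532.v6.1, on the minus strand of chromosome 2 at 7880570 to 7887119 with 13 exon blocks, went from 1.56 ± 0.1 to 26.7 ± 0.669 CPM (log2 4.10, SE 0.11). The lowest was Cre09.g392867_4532.v6.1, on the minus strand of chromosome 9 at 301052 to 316892 with 11 exon blocks. It went from 122 ± 10.4 to 9.32 ± 0.737 CPM (log2 -3.70, SE 0.08). Cre17.g696700_4532.v6.1, on the plus strand of chromosome 17 at 100933 to 103134 with 3 exon blocks, went from 31.5 ± 3.50 to 3.17 ± 0.186 CPM (log2 -3.30, SE 0.12). Adjusted p-values of these 4 genes ranged from 2e-15 to 3.4e-11 (edgeR quasi-likelihood test, Benjamini-Hochberg). The products of these genes are not known from the tables used here.

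Counts from the mitogenome were 243 ± 35.5 CPM in crpaf1-1 and 144 ± 27.7 CPM in wild type (SD, n = 3), and every crpaf1-1 library was above every wild-type library (exact permutation p = 0.1, the smallest possible). All 8 genes also passed when adjusted over the list alone. The set did not pass against other genes with camera (adjusted p = 0.0626, and adjusted p = 0.959 with an estimated correlation). Counts from the plastome were 331 ± 118 CPM in crpaf1-1 and 316 ± 95.3 CPM in wild type (exact permutation p = 1, n = 3), and 54 of its 63 tested genes did not pass, with a median log2 fold change of -0.07 (SD 0.46). Leaving out crpaf1-1 replicate 1 or wild type replicate 3 brought the number of higher mitogenome genes to 5. The plastome genes lower in crpaf1-1 numbered 6, but 15 without crpaf1-1 replicate 3 (median -0.40), 12 without wild type replicate 3 (median -0.29), and 3 without crpaf1-1 replicate 2, wild type replicate 1 or wild type replicate 2. In lane 2 alone, 6710 genes changed between crpaf1-1 and wild type, and lane 3 held 1 library per group.

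The values of crpaf1-1 and wild type did not overlap for 8568 genes (64.1%, where chance gives 10%). Scaling by library size alone moved the median of all genes to 0.09 and the share of called genes that were higher from 48.9% to 60.3%.

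The comparison of crskip-1 with wild type asks the same of SKIP. Of 13376 genes, 6618 (49.5%) changed, 3259 of them higher and 3359 lower, with a median absolute log2 fold change of 0.42. Among the 921 genes that changed at least 2-fold, 677 (73.5%) were lower and 244 higher. Of the plastome's 63 tested genes, 54 were lower and the other 9 did not pass, with a median log2 fold change of -1.69 (SD over genes 0.68). As a set they stood apart from other genes with camera (adjusted p = 4.66e-09), but not with the correlation among them estimated (adjusted p = 0.876 with an estimated correlation).

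Plastome counts were 113 ± 5.6 CPM in crskip-1 against 316 ± 95.3 CPM in wild type (SD, n = 3), and wild type was 2.80-fold higher. The wild-type libraries gave 392, 345 and 209 CPM and the crskip-1 libraries 119, 108 and 111 CPM, without overlap (exact permutation p = 0.1, the smallest possible). In lane 3 the values were 392 CPM in wild type and 119 CPM in crskip-1. In lane 2 alone 39 of 61 plastome genes were lower, with a median log2 fold change of -1.43. Adjusted over the list alone, 57 were lower. In the mitogenome, 5 of 8 genes were higher in crskip-1 (6 adjusted over the list alone), with a median log2 fold change of 0.43 (SD 0.26). Its counts were 169 ± 12.6 CPM in crskip-1 and 144 ± 27.7 CPM in wild type, a difference that did not pass (exact permutation p = 0.3, n = 3), nor did camera (adjusted p = 0.365). The 5 higher mitogenome genes became 2 without wild type replicate 2, wild type replicate 3 or crskip-1 replicate 1, 3 without crskip-1 replicate 2, and 2 with library size alone.

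**Figure D1:**
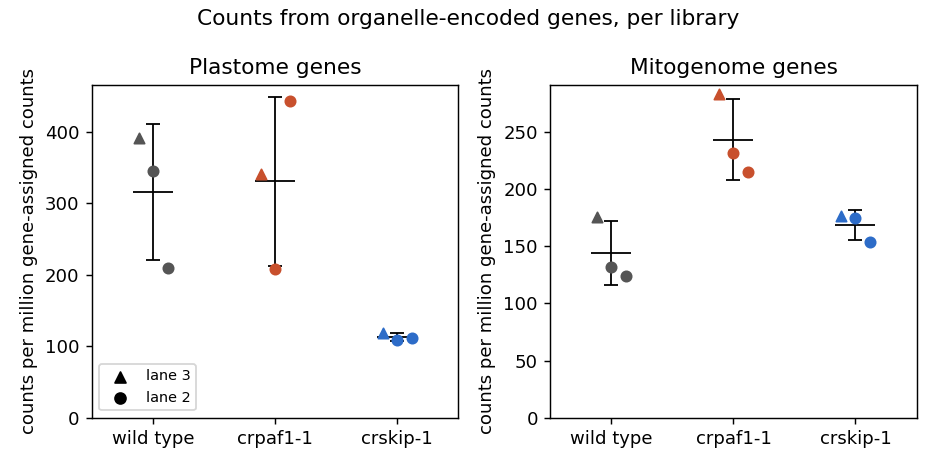
Counts from plastome genes (left) and mitogenome genes (right), in CPM, per library of wild type, crpaf1-1 and crskip-1; triangles are lane 3, circles lane 2, horizontal bars the mean and error bars the SD (n = 3). The plastome values of crskip-1 lay at 108 to 119 CPM, below the 208 CPM of the lowest library of the other groups.

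Among nuclear genes, Cre14.g623250_4532.v6.1, a single exon block on the minus strand of chromosome 14 at 2382748 to 2385580, had the highest fold change under the naming rule. It went from 2.14 ± 0.251 CPM in wild type to 11.2 ± 0.754 CPM in crskip-1 (SD, n = 3; log2 2.39, SE 0.15). Cre06.g278186_4532.v6.1, on the minus strand of chromosome 6 at 3875169 to 3882617 with 15 exon blocks, went from 5.83 ± 0.620 to 29.8 ± 0.993 CPM (log2 2.35, SE 0.11). The lowest was Cre06.g281600_4532.v6.1, on the minus strand of chromosome 6 at 4995242 to 5000705 with 7 exon blocks. It went from 50.2 ± 29.8 to 4.68 ± 4.26 CPM (log2 -3.42, SE 0.60), with a wide spread in both groups, and its log2 fold change was -4.52 without crskip-1 replicate 1. Cre04.g223300_4532.v6.1, on the plus strand of chromosome 4 at 2681827 to 2685518 with 5 exon blocks, went from 40.3 ± 22.1 to 4.03 ± 3.12 CPM (log2 -3.31, SE 0.50). Its log2 fold change was -4.18 without crskip-1 replicate 1. It overlaps 2 genes on the opposite strand, and its counts are uncertain for that reason. Adjusted p-values of these 4 genes ranged from 4.3e-11 to 0.00014 (edgeR quasi-likelihood test, Benjamini-Hochberg).

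The values of crskip-1 and wild type did not overlap for 7550 genes (56.4%, where chance gives 10%), and in lane 2 alone 5660 genes changed. Scaling by library size alone moved the median of all genes to -0.12 and the share of called genes that were higher from 49.2% to 27.6%, so the balance of higher and lower genes holds relative to that shift.

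The direct comparison of crpaf1-1 with crskip-1 asks where the effects of the mutations differ. Of 13376 genes, 7202 (53.8%) differed, 3433 of them higher and 3769 lower in crpaf1-1. At 2-fold or more, 533 were higher and 399 lower in crpaf1-1. Of 63 plastome genes, 52 were higher in crpaf1-1 (57 adjusted over the list alone), with a median log2 difference of 1.59 (SD 0.54). Camera gave the set an adjusted p of 1.3e-08, and adjusted p = 0.994 with an estimated correlation. Plastome counts were 331 ± 118 CPM in crpaf1-1 and 113 ± 5.6 CPM in crskip-1 (SD, n = 3; exact permutation p = 0.1, the smallest possible).

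In the mitogenome 7 of 8 genes did not differ past the threshold between the mutants, with a median log2 difference of 0.25 under TMM scaling. Its summed counts, taken without TMM, were 1.44-fold higher in crpaf1-1, at 215 to 283 CPM against 154 to 177 CPM (exact permutation p = 0.1, the smallest possible, n = 3). The 2 measures are scaled differently, so part of the gap between them comes from scaling. Of 677 genes with a single exon block, 257 were higher in crpaf1-1 than in crskip-1, 107 were lower and 313 did not pass, with a median log2 difference of 0.18 (camera adjusted p = 0.0254, and adjusted p = 0.994 with an estimated correlation). The single exon block set was not limited to nuclear genes, so its difference may in part repeat that of the plastome. In lane 2 alone 6174 genes differed. With library size alone the median of all genes moved to 0.20 and the share of called genes higher in crpaf1-1 went from 47.7% to 76.7%.

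Cre12.g544450_4532.v6.1, on the minus strand of chromosome 12 at 9070762 to 9077311 with 9 exon blocks, measured 165 ± 15.6 CPM in crpaf1-1, 12.4 ± 0.385 CPM in crskip-1 and 14.2 ± 0.464 CPM in wild type (SD, n = 3). The mutants differed by log2 3.73 (SE 0.08). Cre09.g407950_4532.v6.1, on the plus strand of chromosome 9 at 5366217 to 5368948 with 6 exon blocks, measured 19.0 ± 2.55, 1.57 ± 0.264 and 1.78 ± 0.150 CPM in the same order (log2 difference 3.59, SE 0.15). Cre06.g278186_4532.v6.1, which was higher in crskip-1, was lower than wild type in crpaf1-1, at 2.15 ± 0.5 CPM (log2 -1.45 against wild type, SE 0.15), and the mutants differed by log2 -3.80 (SE 0.12). Cre09.g392867_4532.v6.1 was lower in both mutants and lowest in crpaf1-1 (log2 difference -2.92, SE 0.09). Adjusted p-values of these 4 differences ranged from 1.3e-15 to 9.2e-12 (edgeR quasi-likelihood test, Benjamini-Hochberg).

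The overlap of the mutants' changes bears on the module named in the title. In all, 3723 genes changed in the same direction in both mutants, 1642 higher and 2081 lower, and 826 changed in opposite directions. At 2-fold or more in both mutants, 440 shared a direction and 23 were opposite. Independent lists of these sizes would share 930 higher and 1001 lower genes and hold 1930 in opposite directions. Of the opposite genes, 337 were higher in crpaf1-1 and lower in crskip-1 and 489 the reverse. Cre17.g696700_4532.v6.1 was among the shared changes, at log2 -3.30 (SE 0.12) in crpaf1-1 and -3.19 (SE 0.13) in crskip-1, with a difference between mutants of -0.11 (SE 0.17) that did not pass.

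Changes of shared direction were often unequal in size, since 1731 of the 3723 genes differed between the mutants. Another 3257 genes were called in crpaf1-1 alone, of which 2425 differed between the mutants, and 2069 in crskip-1 alone, of which 1612 did. Across genes the log2 fold changes of the mutants correlated at r = 0.53 and rho = 0.47. Unchanged groups simulated with shared controls gave a mean r of 0.51 and rho of 0.474, and at most 2 genes called in the same direction. The covariance was 0.192 against a simulated 0.00984, a difference of 0.183. The 3 controls do not split into parts of 2 libraries, so part of the excess of shared calls may come from the shared controls.

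**Figure D2:**
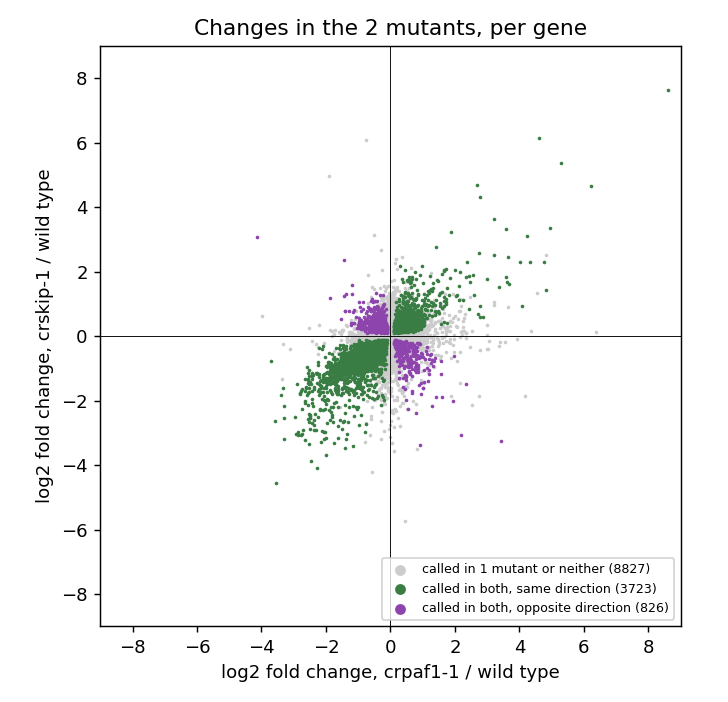
Log2 fold change against wild type of each of 13376 genes in crpaf1-1 (horizontal axis) and crskip-1 (vertical axis), each from 3 libraries per group. Green points are the 3723 genes called in both mutants in the same direction, purple points the 826 called in opposite directions and grey points all others.

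Gene structure was set beside the fold changes because elongation and splicing act along the gene. Among long transcripts, more genes were lower than higher in both mutants. In the longest of 5 classes of exonic length (4783 bases and over), 36.4% of genes were lower and 21.9% higher in crpaf1-1, and 35.0% lower and 14.0% higher in crskip-1. In the shortest class (1830 bases and under), 23.4% were lower and 32.3% higher in crpaf1-1, and 18.8% lower and 28.8% higher in crskip-1. Genes with a single exon block (677 genes) had a median log2 fold change of 0.14 in crpaf1-1, with 35.7% higher and 17.4% lower, and the set did not pass against other genes (camera adjusted p = 0.0626, and adjusted p = 0.959 with an estimated correlation). In crskip-1 the same genes had a median of -0.01, with 20.8% higher and 27.3% lower. The set was not limited to nuclear genes, and 54 of 63 tested plastome genes were lower in crskip-1. Its values without organelle genes were not worked out, so its lower genes may in part repeat the plastome result. Genes with over 20 exon blocks (990 genes) had medians of -0.10 in crpaf1-1 and -0.08 in crskip-1.

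The correlation of log2 fold change with exonic length across genes was -0.116 in crpaf1-1 and -0.151 in crskip-1 (permutation p = 1e-05 each, the smallest 100000 resamples can give; adjusted p = 1.5e-05). With exon number and mean expression held fixed it was -0.068 in crpaf1-1 and -0.137 in crskip-1. The difference between the mutants did not correlate with length (rho = 0.001, permutation p = 0.9, adjusted p = 0.9). Exon blocks correlated at -0.105 in crpaf1-1 (adjusted permutation p = 1.5e-05) and -0.021 in crskip-1 (permutation p = 0.02, adjusted p = 0.022), and at -0.116 with the difference between them (adjusted permutation p = 1.5e-05). With length and mean expression held fixed the correlation with exon blocks was -0.066 in crpaf1-1 and turned to 0.021 in crskip-1. Span, the gene's extent on the chromosome, gave -0.078 in crpaf1-1, -0.086 in crskip-1 and -0.020 for their difference. In lane 2 alone the correlations with length were -0.123 in crpaf1-1 and -0.158 in crskip-1.

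Libraries also separated by length one at a time. Each library's correlation of length with log2 expression relative to the mean of all libraries averaged 0.134 ± 0.055 in wild type, -0.064 ± 0.037 in crpaf1-1 and -0.087 ± 0.038 in crskip-1 (SD, n = 3; exact permutation p = 0.1 for each mutant against wild type, the smallest possible, and 0.5 between mutants). For exon blocks the means were 0.069 ± 0.071, -0.111 ± 0.044 and 0.046 ± 0.028 (exact permutation p = 0.1 for crpaf1-1 and 0.6 for crskip-1 against wild type, n = 3). The crskip-1 correlation with exon blocks no longer passed without wild type replicate 2 (-0.014), wild type replicate 3 (-0.001), crskip-1 replicate 1 (-0.015) or crskip-1 replicate 2 (-0.009).

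**Figure D3:**
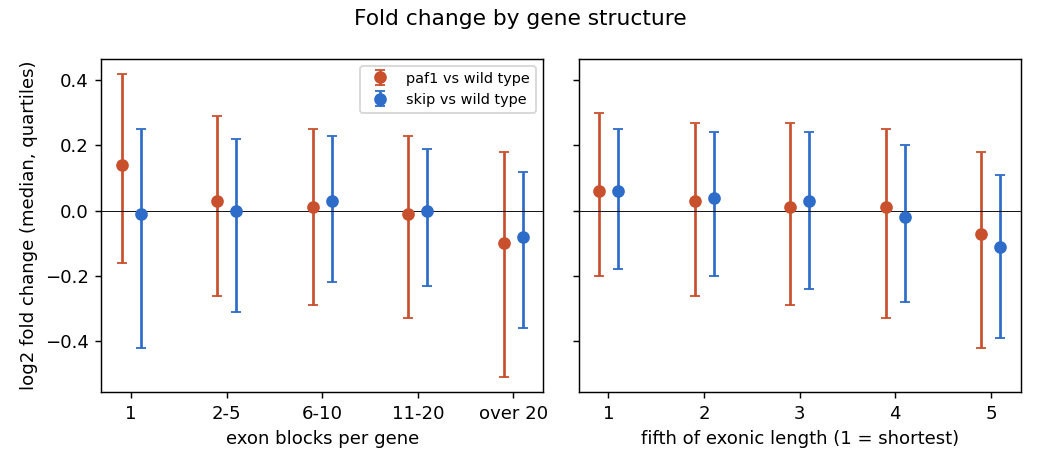
Median log2 fold change against wild type (points) with quartiles (bars) of genes grouped by exon blocks (left) and by 5 equal classes of exonic length from the shortest (1) to the longest (5) (right), for crpaf1-1 in red and crskip-1 in blue. Medians fell from 0.06 in the shortest class to -0.07 in crpaf1-1 and -0.11 in crskip-1 in the longest.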

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

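The tests on the plastome and on the changes shared by the mutants were chosen only after the results were seen, as was the requirement that a length test pass its bound by more than its spread; the bounds for length and the splits of the libraries were set before.

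The mutants differed from each other in 7202 genes, and 826 genes were called in opposite directions against wild type, 23 of them at 2-fold or more in both mutants. The tested differences between mutants (log2, crpaf1-1 over crskip-1) include each printed gene that differed. They were 3.39 for Cre12.g537250_4532.v6.1, 3.15 for Cre02.g145750_4532.v6.1, 3.73 for Cre12.g544450_4532.v6.1 and 3.59 for Cre09.g407950_4532.v6.1. Lower in crpaf1-1 were Cre09.g392867_4532.v6.1 at -2.92, Cre14.g623250_4532.v6.1 at -2.22 and Cre06.g278186_4532.v6.1 at -3.80. The differences of Cre06.g281600_4532.v6.1 (2.26, SE 0.64) and Cre04.g223300_4532.v6.1 (1.56, SE 0.57) came with a wide spread between replicates. Without crpaf1-1 replicate 1 they were 1.38 and 0.83 and no longer passed, and without crskip-1 replicate 1 they were 3.37 and 2.43. That of Cre04.g223300_4532.v6.1 also did not pass without crskip-1 replicate 2 (1.26) or crskip-1 replicate 3 (1.28), or with DESeq2 (adjusted p = 0.084). Both differences passed with the replicate number as a block, at 2.26 and 1.55 (adjusted p = 9.7e-06 and 0.00035, edgeR quasi-likelihood test). They also passed in lane 2 alone, at 2.49 and 1.70. Leaving out replicate 1 of 1 group also unbalances the lanes. The correlation of the difference between mutants with exon blocks was -0.116.

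The plastome was flagged because 52 of its 63 tested genes were higher in crpaf1-1 than in crskip-1, with crskip-1 below wild type as well. Scaling does not account for it, since the median log2 fold change of plastome genes in crskip-1 was -1.81 with library size alone. Nor does a carry-over of organelle RNA through poly(A) selection that acts on both organelles alike, since the median of the mitogenome genes was 0.43 (SE over genes 0.09). That SE takes the 8 genes as independent, though their estimated correlation was 0.685. Summed mitogenome counts were not lower in crskip-1 either, at 169 ± 12.6 CPM against 144 ± 27.7 CPM in wild type (exact permutation p = 0.3, n = 3). Plastid DNA in the wild-type libraries was tested as an even loss per kb from each gene, and the SD of the log2 loss per kb over 63 genes was 1.58. That SD includes count noise, and only 21 plastome genes passed the filter of 5 CPM in at least 3 libraries. The test therefore does not decide on plastid DNA. A carry-over of plastid RNA alone, a difference in polyadenylation of plastid transcripts and a lower level of plastid RNA in crskip-1 stay open and were not tested.

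Changes shared by both mutants were more numerous than independent lists give. Shared wild-type libraries alone do not account for them, since the covariance of the log2 fold changes was 0.192 and unchanged groups simulated with shared controls reached 0.0111 at most. A wild type set apart from both mutants is not the whole of the changes, given the 7202 genes that differed between the mutants. For the 3723 genes of shared direction it cannot be told apart from an effect common to both mutations: 46.5% of them differed between the mutants, but an offset of the wild-type cultures would add to both comparisons whatever each mutant does. A shared effect of the mutations, and a shared difference in growth or in timing of harvest, stay open and were not tested.

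Of the 10 splits of the 6 libraries in each comparison, 1 called as many genes as the real grouping, the real one itself. The real groupings called 7806 genes for crpaf1-1 against wild type, 6618 for crskip-1 against wild type and 7202 between the mutants, and the highest other split called 0 in each with edgeR. At an unadjusted p under 0.05 the other splits gave 62 to 321, 155 to 477 and 132 to 431 genes. With 10 splits the share is never under 0.1, which is too few to reach 0.05. Every other split also mixed libraries of both groups. Real differences between the groups would then widen the spread within its parts and keep its calls low. The counts of the other splits therefore do not measure chance.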

How the results depend on the processing

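Lane as a term, lane 2 alone, the length correlation at fixed exon number and the organelle counts under each alternative were chosen after the data were examined. Leaving aside the 2-fold threshold, changed genes numbered 6710 to 8176 for crpaf1-1, 5660 to 7004 for crskip-1, 6174 to 8249 between mutants and 3044 to 4022 in the same direction in both. With the 2-fold threshold they were 1178, 921, 932 and 440, fewer by construction, with 2 mitogenome genes higher in crpaf1-1 and 0 in crskip-1. Genes called in opposite directions numbered 826 in the main fit, 23 with the 2-fold threshold and 1102 with library size alone. The stricter filter left 21 plastome genes, 17 of them lower in crskip-1 and 20 higher in crpaf1-1 than in crskip-1. With library size alone 2 mitogenome genes were higher in crskip-1. The median log2 fold change of all genes moved to -0.12 there, and that of the mitogenome genes from 0.43 to 0.31. The loss of calls thus came with a shift of all genes. The correlation with exon blocks in crskip-1 turned to 0.021 with length and mean expression held fixed. That with length stayed at -0.137 with exon number and mean expression held fixed. No negative correlation with exon blocks thus remained in crskip-1 beside that with length and mean expression. Of 26 called values of the 10 printed genes, 21 passed in the same direction under all 19 alternatives and 0 reversed. The others lost the call in 12 cases, 10 of them for Cre06.g281600_4532.v6.1 and Cre04.g223300_4532.v6.1 in comparisons with crpaf1-1.

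Leaving out 1 library gave 7068 to 7924 genes for crpaf1-1, 5849 to 6548 for crskip-1, 6421 to 7318 between mutants and 3215 to 3575 in shared direction. Plastome genes lower in crskip-1 numbered 49 to 59, and those higher in crpaf1-1 than in crskip-1 43 to 59. Higher mitogenome genes numbered 5 to 8 in crpaf1-1 and 2 to 7 in crskip-1. The crskip-1 correlation with exon blocks ranged from -0.049 to -0.001.

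Libraries of replicate number 1 deviated alike, which cannot be told apart from lane 3, since that lane held number 1 alone (lane as a term called 120 genes). Numbers 2 and 3, both in lane 2, showed no clear pairing across genes. In every group the library's correlation with exonic length was lowest in number 1 and highest in number 3. The numbers may thus carry a shared effect. Deviations of same-numbered libraries correlated at 0.12 to 0.26 for number 1, -0.02 to 0.06 for 2 and -0.05 to 0.13 for 3. With the replicate block 8176, 7004 and 7579 genes were called and 4022 shared a direction. The adjusted p of Cre06.g281600_4532.v6.1 in crskip-1 against wild type went from 0.00014 to 2.7e-08 with it (edgeR quasi-likelihood test). The tests fixed beforehand for the mutated genes and the gene lists were not run, since no gene could be named. In simulated data 48% of changes of log2 0.32 were recovered. Far fewer genes changed there than were called here, and the Benjamini-Hochberg adjustment depends on how many genes change. That share therefore does not carry over to these comparisons, and how often small changes were missed in them is not known.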

Other observations

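The tests on neighbouring genes and on genes near 0 counts were chosen after the data were examined; the bounds of the length tests were set before, and the requirement to pass them by the spread, and the use of the stricter filter for them, were added after.

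Genes next to each other on a chromosome or organelle genome tended to change alike. Pairs within the plastome and mitogenome were not set apart. Plastome genes fell together in crskip-1 (median log2 -1.69), which may raise its correlations. Across adjacent pairs the Spearman correlation of log2 fold changes was 0.069 in crpaf1-1 and 0.083 in crskip-1, and at 10 genes apart it was -0.016 and -0.001. By orientation, divergent pairs (3590), whose starts face each other, correlated at 0.146 in crpaf1-1 and 0.101 in crskip-1, and tandem pairs (6165) at 0.057 and 0.118. Adjusted permutation p-values were 2e-05 to 3e-05, over 6 correlations and with pairs that are not independent replicates. Convergent pairs (3583) correlated at 0.009 and 0.005, which did not pass (adjusted permutation p = 0.72 and 0.80). Overlapping neighbours can share reads where strand is not used. Without them, divergent pairs (2393) correlated at 0.117 and 0.101, tandem pairs (4902) at 0.066 and 0.127, and convergent pairs (2119) at 0.019 and 0.027.

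A set of 16 genes had at most 3 counts over all libraries of 1 group and at least 15 in every library of another. Of these, 10 were at that floor in wild type, 8 of them present in crpaf1-1 and 4 in crskip-1. The number at the floor in a mutant and present in wild type was 0. Between the mutants, 6 were at the floor in crskip-1 and present in crpaf1-1, and 2 the reverse. Of 865 tested genes with no locus tag in the v5.5 table, 251 were higher and 212 lower in crpaf1-1, and 158 higher and 189 lower in crskip-1, and camera did not set them apart from other genes in either (adjusted p = 0.976 and 0.994). The 14 listed genes of the plus mating type locus held 34 counts in all, 9 in wild type, 15 in crpaf1-1 and 10 in crskip-1.

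Log2 fold changes fell weakly with exonic length in both mutants. Low counts are argued against as the whole cause in crskip-1. With the stricter filter the correlations were -0.116 in crpaf1-1 and -0.180 in crskip-1. Among genes in the upper part of mean expression they were -0.081 and -0.183 (spread 0.012 each). The bound set before was -0.08, which crskip-1 passed by more than its spread and crpaf1-1 did not, so for crpaf1-1 the exclusion rests on the stricter filter, brought in after that value was seen. Chance differences in RNA integrity between single libraries would let the libraries overlap. The closest libraries of crskip-1 and wild type lay 2.65 pooled SDs apart, and 2.05 with the least favourable library left out. Those of crpaf1-1 and wild type lay 2.19 apart but 1.69 with 1 library left out. With a library left out, only crskip-1 passed the bound set before for this gap. The SDs rest on 3 libraries per group, and the exact permutation p was 0.1 for each mutant, the smallest possible. They also hold a rise from replicate 1 to replicate 3 that every group showed. It went from 0.081 to 0.191 in wild type, from -0.092 to -0.022 in crpaf1-1 and from -0.110 to -0.044 in crskip-1. Pairing by replicate number was not used for the gaps, so they do not set the 2 mutants apart from each other. Chance therefore stays open for both mutants. RNA integrity that differs between cultures of a whole group, and an effect of the mutations on long transcripts, were not tested. Both mutants were compared with the same 3 wild-type libraries. A wild type that stands apart in length therefore cannot be told from a trend in both mutants.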
